A study of Homo sapiens with 24 samples.

How the data were processed

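The series holds RNA-seq of LNCaP cells in 2 studies of 4 groups each, with 3 libraries per group, and all 24 libraries were used. Per the labels' protocols, cells were transfected with a vector or an siRNA, moved the next day to androgen-deprived medium and, a day later, given 5 nM R1881 or ethanol for 48 h. RNA was taken with Trizol and columns, and poly(A) libraries were made and sequenced by a company. The labels describe biological triplicates. The titles carry sample numbers (S1 to S38), and no label says that a run of these marks a shared culture or day.

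The deposited values are raw read counts per gene, in 1 table of 60649 features. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, aligned with STAR 2.7.9a and counted with featureCounts of Subread 1.6.4 on GRCh38.p7. The strand setting, the handling of reads with several alignments and the annotation release are not given in the sources used here, so antisense and overlapping genes, and families of near-identical genes, are uncertain. 3 columns of the P3 group with R1881 also carry the word siRNA in the table, and were matched by sample number to the titles, which name P3 alone. 140 symbols stand on more than 1 feature, and all tests were run per feature ID. Coordinates were taken from GENCODE 29 (GRCh38), in which 58381 of the IDs are found. Genes of the Y chromosome and XIST were tested with the rest but are not named or plotted. No authors' list of genes or statistic was used here.

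Depth was 16665915 to 24260446 counts per library. A count of 0 allows up to 3 counts, 0.124 CPM in the deepest library. Where a whole group had no count, the fold was computed against 3 counts over the group and is given as a lower bound, and where it had up to 3 counts, the ratio of scaled counts is given with its 95% exact interval for a ratio of counts. The share of mitochondrially encoded counts in a single library has a Wilson interval. Reads carry no molecular identifiers, so these intervals and floors cover counting error only. Libraries of a group were compared with a chi-square of their counts over genes, and none were identical or within sampling noise of each other.

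Levels are CPM over library sizes scaled by TMM within each study, as mean ± SD of 3 libraries, and the floor in CPM of a count of 0 uses the unscaled total. The TMM factors of study 2 were lower in every R1881 than in every vehicle library (0.893 in siWDR77_R1881 S24 to 1.11 in siCtrl_vehicle S7), so unscaled CPM would give smaller rises with hormone. Tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group, a mean per group and no covariate, and the robust quasi-likelihood F test, fitted on the 12 libraries of each study (17772 and 17893 genes). A gene is called at a Benjamini-Hochberg adjusted p under 0.05. Per study there are 2 comparisons of R1881 with vehicle, 2 between arms and the difference in response between arms, 10 in total. Log2 fold changes come from the fit, with SE from the quasi-likelihood F statistic.

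19 gene lists were fixed from textbook knowledge, of which 18 are reported: androgen-induced and androgen-repressed genes, cholesterol and fatty acid synthesis, DNA replication, mitosis, p53 targets, the PRMT5 methylosome and Sm ribonucleoprotein assembly, the unfolded protein and amino acid stress response, the interferon response, immediate early and heat shock genes, neuroendocrine, luminal, basal, and fibroblast and mesenchymal markers, hypoxia and glycolysis, ribosome biogenesis and MYC targets, polyamine and one-carbon metabolism, and mitochondrially encoded genes. A few genes, such as GNMT, stand in 2 lists. Each list was tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Members called over all genes were counted, and again after adjusting over the list alone.

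The size of the response was tested with camera on genes chosen in the control arm of the other study at an adjusted p under 0.05 and a log2 fold change of at least 1 in either direction, adjusted over the 4 tests of the 2 studies. Overlaps of calls between studies were set against n1 × n2 / N for independent lists and tested with Fisher's exact test across genes.

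The genes named are, in each comparison, WDR77, KLK3, KLK2, TMPRSS2 and FKBP5, then from the 10 largest changes per direction among called genes with a mean of at least 1 CPM in the higher group and the 3 libraries of a group all above those of the other, and from the 4 members of each list with the smallest adjusted p. The remaining list and some genes that this rule would name are not reported here. The groups, tests, lists, this rule and the alternatives listed next were fixed before the data were examined. The alternatives were RLE size factors in place of TMM, no filter on low counts, DESeq2 1.42.0, a block for the run of the sample number, only the 6 libraries compared, all 24 libraries in 1 fit, each library left out in turn, and stricter thresholds for the lists and overlaps. The sample numbers fall in 3 runs, with 1 library of each group in each. Deviations from the group means correlated at over 0.1 in all 3 pairs of one run for R1881 in P3 cells (lowest 0.324), P3 against EV in R1881 (0.205) and the siRNAs in R1881 (0.171), so in these comparisons the runs are taken to pair the libraries, from the data and not from a label. In the other 5 comparisons of 2 groups at least 1 pair lay under that value. Fits without library S35 of siCtrl_vehicle in comparisons that do not include it, and in the lists, responses and overlaps, were added after the data were seen.

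The fit was tested on simulated counts with 200 changed genes. For P3 against EV in R1881 it recovered 74% of genes changed 1.5-fold and 92% of genes changed 2-fold, for the difference in response in study 1 54% and 80%, for the siRNAs in R1881 60% and 82%, and for the difference in response in study 2 38% and 64%. Of unchanged genes it called 0.0411%, 0.0411%, 0.0942% and 0.0177%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.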

Results

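RNA-seq read counts per gene were analysed in 24 libraries of LNCaP, a human prostate cancer cell line that responds to androgen. The series is about WDR77, a WD-repeat protein that acts as a coregulator of androgen-driven transcription and pairs with the arginine methyltransferase PRMT5. In study 1 the cells were transfected with an empty vector (EV) or with a construct encoding WDR77-peptide 3 (P3), and in study 2 with a control siRNA (siCtrl) or an siRNA against WDR77 (siWDR77). They then received R1881, a synthetic androgen, or the ethanol vehicle. Each of the 8 groups held 3 libraries. Mitochondrially encoded genes took 5.15% to 6.3% of counts, except for 8.4% in siCtrl_vehicle S35 (95% Wilson interval 8.39% to 8.42%).

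WDR77 itself was measured first. Its gene lies on chromosome 1 at 111439890 to 111449376 on the minus strand (GRCh38, GENCODE 29), head to head with ATP5PB, a subunit gene of ATP synthase, with which it overlaps over 513 bases. In study 2 its level was 45 ± 2.85 CPM (mean ± SD, n = 3) in siCtrl_vehicle, with single libraries at 46.7, 46.6 and 41.7 CPM, and 65.7 ± 1.76 CPM in siCtrl_R1881, with libraries at 67.3, 66.1 and 63.8 CPM. The siRNA lowered it to 13.2 ± 1.8 CPM in vehicle, with libraries at 14.9, 13.3 and 11.3 CPM, and to 14.3 ± 1.17 CPM in R1881, with libraries at 15.6, 13.4 and 13.8 CPM. In study 1 WDR77 stood at 59.2 ± 4.24 CPM in EV_vehicle (libraries at 55.1, 58.8 and 63.6 CPM), 60.8 ± 2.84 CPM in EV_R1881 (libraries at 58.8, 59.4 and 64 CPM) and 56.7 ± 4.64 CPM in P3_vehicle (libraries at 61.6, 52.3 and 56.2 CPM). It was higher in P3_R1881, at 94.8 ± 5.61 CPM (libraries at 100.5, 94.7 and 89.3 CPM). Whether a plasmid transcript of the peptide was counted there is not known.

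The other genes followed throughout were 4 well-known androgen-induced genes. Among these were KLK3, the gene of prostate-specific antigen (chromosome 19, 50854915 to 50860764, plus strand) and its neighbour KLK2 (50861568 to 50880567, plus strand). The others were the serine protease gene TMPRSS2 (chromosome 21, 41464551 to 41531116, minus strand) and the co-chaperone gene FKBP5 (chromosome 6, 35573585 to 35728583, minus strand). All are protein-coding, and each value below is a count over the whole gene. In vehicle, KLK3 stood at 1326 ± 55 CPM in EV cells (mean ± SD, n = 3) and at 154 ± 87.3 CPM in siCtrl cells, and with R1881 at 6865 ± 401 and 7833 ± 176 CPM.

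**Figure D1:**
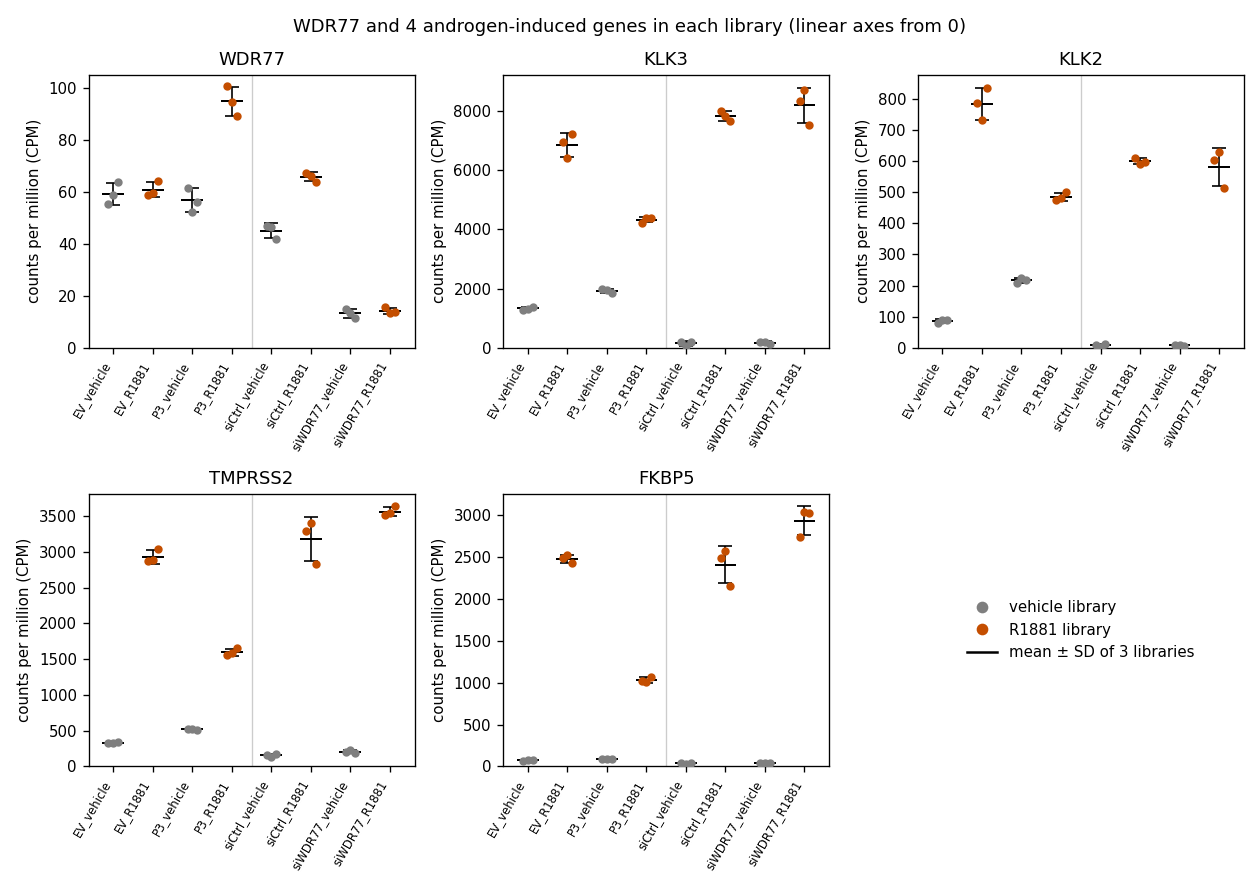
Level of WDR77, KLK3, KLK2, TMPRSS2 and FKBP5 in each library, as TMM-scaled CPM on linear axes that start at 0, in the 8 groups. Each point is a library, and the bars give the mean and SD of the 3 libraries of a group. WDR77 lay at 13.2 ± 1.8 CPM in siWDR77_vehicle against 45 ± 2.85 CPM in siCtrl_vehicle.

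The first comparison asked what R1881 changed in empty-vector cells. FKBP5 rose by 5.07 ± 0.057 on the log2 scale (33.6-fold), KLK2 by 3.19 ± 0.058, TMPRSS2 by 3.15 ± 0.049 and KLK3 by 2.37 ± 0.050 (here and below, ± SE of the fitted log2 fold change, 3 libraries per group). WDR77 differed by 0.037 ± 0.069 (edgeR adjusted p = 0.68). The edgeR quasi-likelihood test called 9130 of 17772 genes, 4432 higher and 4698 lower, and 1262 and 1390 of them by at least 2-fold. SLC2A3, a glucose transporter gene, and SLC26A3, an intestinal anion exchanger gene, had no count in the vehicle libraries and were at least 299-fold and 63.5-fold higher with R1881. ASZ1, a germ-cell gene, had none with R1881 and was at least 40.6-fold lower (floor of 3 counts over the group).

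Of the 34 androgen-induced genes measured, 34 rose (also adjusted over the list alone), among them the metalloreductase gene STEAP4 (10.6 ± 0.14) and the acyl-CoA synthetase gene ACSL3 (3.62 ± 0.052). The list's median change was 3.17 (limma camera adjusted p = 1.20e-43; adjusted p = 0.00115 with an estimated correlation). Of 13 androgen-repressed genes, 11 fell (adjusted over the list alone 11), CAMK2N1, an inhibitor of CaM kinase II, among them (-3.29 ± 0.086). The list had a camera adjusted p of 3.08e-06, and adjusted p = 0.071 with an estimated correlation. UGT2B28 and UGT2B11, members of the androgen-glucuronidating family counted in that list, went the other way and rose (4.55 ± 0.15 and 3.15 ± 0.11). The UGT2B genes share much sequence, so each one's count is uncertain. Of 29 genes of cholesterol and fatty acid synthesis 28 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.99e-26). The fatty acid elongase gene ELOVL5 rose by 2.56 ± 0.050 and the sterol sensor gene INSIG1 by 2.25 ± 0.054.

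Cell-cycle genes moved down. Each of the 33 replication genes fell (adjusted over the list alone 33), with the helicase subunit genes MCM2 at -1.7 ± 0.067 and MCM4 at -1.54 ± 0.058. Of the mitosis genes 28 of 29 fell (adjusted over the list alone 28), with the survivin gene BIRC5 at -1.98 ± 0.065 and the topoisomerase gene TOP2A at -1.78 ± 0.060. Camera gave these 2 lists adjusted p = 1.28e-24 and 5.42e-25, and both stayed called with an estimated correlation (adjusted p = 0.017 for each). Of 23 p53 targets 17 fell, such as the sestrin gene SESN1 (-1.71 ± 0.062), and 2 rose, 1 of them the death receptor gene TNFRSF10B (1.57 ± 0.049), with the same counts adjusted over the list alone (camera adjusted p = 0.000975; adjusted p = 0.0524 with an estimated correlation). Of 20 ribosome biogenesis genes and MYC targets 14 fell (adjusted over the list alone 15 lower and 1 higher), the rRNA methyltransferase gene FBL at -0.89 ± 0.063 and MYC at -0.68 ± 0.058 (camera adjusted p = 3.68e-05; adjusted p = 0.147 with an estimated correlation). In the list of the PRMT5 methylosome and Sm ribonucleoprotein assembly, 14 of 20 members fell and 2 rose (the same counts adjusted over the list alone), GEMIN4 of the SMN complex at -0.83 ± 0.062 (camera adjusted p = 0.00272; adjusted p = 0.273 with an estimated correlation).

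The luminal keratin genes KRT8 (3.05 ± 0.054) and KRT18 (2.61 ± 0.059) rose, as did 12 of 15 luminal markers, while 2 fell (the same counts adjusted over the list alone; camera adjusted p = 8.52e-07; adjusted p = 0.0735 with an estimated correlation). Of 24 genes of the unfolded protein and amino acid stress response 18 rose and 4 fell (adjusted over the list alone 18 and 5), the ER stress sensor gene ERN1 by 1.96 ± 0.066 and the ER-associated degradation gene HERPUD1 by 1.3 ± 0.051. Of 16 immediate early and heat shock genes 11 rose (adjusted over the list alone 11 higher and 1 lower), NR4A1, an orphan nuclear receptor, by 2.39 ± 0.092. Camera gave the stress list an adjusted p of 2.72e-08 and the immediate early list 0.000243, and both calls were lost, at adjusted p = 0.0735 with an estimated correlation for each. Of 21 hypoxia and glycolysis genes 12 rose and 5 fell (adjusted over the list alone 14 and 5), the angiogenic factor gene VEGFA by 1.75 ± 0.060 (camera adjusted p = 0.00264; adjusted p = 0.273 with an estimated correlation).

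The remaining lists were not called by camera. Polyamine and one-carbon metabolism had 9 members higher and 5 lower of 18 (the same adjusted over the list alone; camera adjusted p = 0.092). Large rises were those of spermine synthase SMS (3.1 ± 0.053), ornithine decarboxylase ODC1 (2.33 ± 0.049) and glycine methyltransferase GNMT (4.76 ± 0.087), the last of which is in the androgen-induced list too. Fibroblast and mesenchymal markers had 5 higher and 2 lower of 10 (adjusted over the list alone 6 and 2; camera adjusted p = 0.428), ACTA2, smooth muscle actin, at 4.2 ± 0.20 and FN1, fibronectin, at -1.87 ± 0.054. Their median was 0.83 and their mean 1.12, although the rotation test fry put them lower (adjusted p = 0.874). Interferon response genes had 5 higher, the GTPase gene MX1 (1.93 ± 0.10) among them, and 10 lower of 29 (the same adjusted over the list alone; camera adjusted p = 0.277). Neuroendocrine markers had 2 higher and 1 lower of 6, the 1 lower being the neurotensin gene NTS (-4.53 ± 0.18). Basal epithelial markers had 2 higher of 4, and mitochondrially encoded genes 4 higher of 13, with the same counts adjusted over the list alone for all 3 lists (camera adjusted p = 0.636 for neuroendocrine, 0.439 for basal and 0.277 for mitochondrial genes).

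In P3 cells R1881 moved the same targets. FKBP5 rose by 3.53 ± 0.053, TMPRSS2 by 1.62 ± 0.047, KLK3 by 1.17 ± 0.048 and KLK2 by 1.17 ± 0.053. WDR77 rose by 0.74 ± 0.067 (1.68-fold, edgeR adjusted p = 5.36e-12). STEAP4 rose by 8.08 ± 0.13 and ACSL3 by 2.16 ± 0.050. ORM1, an acute-phase glycoprotein gene that shares sequence with ORM2 and is therefore uncertain, had no count in P3_vehicle and was at least 276-fold higher. Lower with R1881 were DOCK10, a guanine nucleotide exchange factor gene (-2.04 ± 0.50), the collagen gene COL5A2 (-1.35 ± 0.10), NTS (-1.16 ± 0.14) and CAMK2N1 (-0.94 ± 0.076). The edgeR test called 3726 genes, 2312 higher and 1414 lower, and 338 and 97 of these by at least 2-fold.

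All 34 androgen-induced genes rose in P3 cells (34 adjusted over the list alone; median 1.66, camera adjusted p = 1.17e-78), and 9 of 13 androgen-repressed genes fell with 2 higher (the same adjusted over the list alone; camera adjusted p = 6.15e-07). Of the synthesis genes of cholesterol and fatty acids 28 of 29 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 7.00e-37), ELOVL5 by 1.48 ± 0.048. Of the replication genes 29 of 33 fell (30 adjusted over the list alone), MCM3 at -0.42 ± 0.055. Of the mitosis genes 28 of 29 fell (28 adjusted over the list alone), the spindle factor gene TPX2 at -0.49 ± 0.057 (camera adjusted p = 1.20e-19 for replication and 1.03e-22 for mitosis). TPX2 lost its call in the fit over all 24 libraries (edgeR adjusted p = 0.0852). The unfolded protein and amino acid stress response had 19 of 24 members higher and 1 lower (19 and 2 adjusted over the list alone), HERPUD1 at 0.82 ± 0.051. The luminal markers had 9 of 15 higher and 1 lower (the same adjusted over the list alone), KRT8 at 2.21 ± 0.053 (camera adjusted p = 1.33e-14 for the stress response and 4.76e-09 for the luminal markers). With an estimated correlation these 7 lists kept adjusted p under 0.05, the highest being adjusted p = 0.0479. Of the immediate early and heat shock genes 6 of 16 rose (9 adjusted over the list alone), NR4A1 by 1.34 ± 0.091. Of the polyamine and one-carbon genes 5 of 18 rose and 3 fell (6 and 3 adjusted over the list alone), SMS by 1.98 ± 0.052 (camera adjusted p = 0.000104 for the early and heat shock and 0.000261 for the polyamine list; adjusted p = 0.0597 and 0.0799 with an estimated correlation).

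Without hormone, P3 cells already differed from empty-vector cells. KLK2 was higher by 1.33 ± 0.056 (2.52-fold), TMPRSS2 by 0.65 ± 0.046, KLK3 by 0.54 ± 0.048 and FKBP5 by 0.27 ± 0.052. WDR77 (-0.063 ± 0.068) was not called (edgeR adjusted p = 0.572). The calls of KLK3 and FKBP5 were lost in the fit over all 24 libraries (edgeR adjusted p = 0.308 and 0.136). Among the largest rises were the immediate early gene FOS (4.09 ± 0.30), the transcription factor gene ATOH8 (4.09 ± 0.69), the chemokine gene CXCL12 (2.8 ± 0.57) and PCA3, a prostate long noncoding RNA (2.6 ± 0.33). PCA3 is antisense to another gene and strandedness of the counting is not known, so its value is uncertain. Lower were NTS (-0.89 ± 0.12) and FBXO2, an F-box protein gene (-0.67 ± 0.10). KLF4, a transcription factor gene of the immediate early list, rose by 0.85 ± 0.12, the stress cytokine gene GDF15 by 0.99 ± 0.062 and MX1 by 0.95 ± 0.10.

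In the list of androgen-induced genes 23 of 34 were higher in P3 cells (adjusted over the list alone 27 higher and 3 lower), the cold channel gene TRPM8 by 1.65 ± 0.10. Camera called the list (median 0.41, adjusted p = 2.66e-21; adjusted p = 0.0138 with an estimated correlation). Of 13 androgen-repressed genes 6 were lower (9 adjusted over the list alone), the prostate-specific membrane antigen gene FOLH1 at -0.26 ± 0.047 and UGT2B15 at -0.51 ± 0.10 (camera adjusted p = 8.30e-08; adjusted p = 0.101 with an estimated correlation). UGT2B15 was not called by DESeq2 (adjusted p = 0.0504). Mitochondrially encoded genes were lower in 10 of 13 (11 adjusted over the list alone), MT-CO3 at -0.26 ± 0.047 and MT-ND6 at -0.23 ± 0.047. MT-ND6 was lost in the fit over all 24 libraries (edgeR adjusted p = 0.222; list camera adjusted p = 2.46e-09; adjusted p = 0.217 with an estimated correlation). Hypoxia and glycolysis genes were higher in 8 and lower in 2 of 21 (10 and 3 adjusted over the list alone), with VEGFA at 0.61 ± 0.060, the hexokinase gene HK2 at 0.61 ± 0.061, BNIP3 at 0.40 ± 0.052 and PDK1 at 0.57 ± 0.070 (camera adjusted p = 9.19e-05; adjusted p = 0.33 with an estimated correlation).

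Small decreases in P3_vehicle were found for 4 of 33 replication genes (the same adjusted over the list alone) and 4 of 20 methylosome and Sm assembly genes (6 adjusted over the list alone), both called by camera (adjusted p = 0.00518 each) and both lost at adjusted p = 0.60 with an estimated correlation. PRMT5 (-0.22 ± 0.058) lost its call without the library EV_vehicle S29 or P3_vehicle S5 (edgeR adjusted p = 0.0652 and 0.0884), and STRAP, an SMN-associated protein gene (-0.19 ± 0.053), without EV_vehicle S1 or P3_vehicle S5 (0.0724 and 0.0969). Interferon response genes had 1 higher and 3 lower of 29 (the same adjusted over the list alone; camera adjusted p = 0.0889). In edgeR's test 2809 genes were called, 1409 higher and 1400 lower, and 488 against 8 by at least 2-fold. The count was 1709 without the library EV_vehicle S1, 1825 without EV_vehicle S15 and 1344 without P3_vehicle S5.

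With R1881 the difference between P3 and empty-vector cells turned over. FKBP5 was lower in P3 cells (-1.27 ± 0.048 on the log2 scale), as were TMPRSS2 (-0.88 ± 0.046), KLK2 (-0.69 ± 0.052) and KLK3 (-0.66 ± 0.047). WDR77 was higher (0.64 ± 0.068, edgeR adjusted p = 2.31e-10). The call of KLK3 was lost in the fit over all 24 libraries (edgeR adjusted p = 0.107). The edgeR test called 6572 genes, 3212 higher and 3360 lower, and 909 and 202 of these by at least 2-fold. LRRTM3, a synaptic leucine-rich repeat gene, was higher by 3.66 ± 0.15 and SI, the sucrase-isomaltase gene of the repressed list, by 3.63 ± 0.28.

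All 34 androgen-induced genes were lower in P3 cells given R1881 (34 adjusted over the list alone; median -0.91, camera adjusted p = 2.36e-44), STEAP4 at -1.35 ± 0.060 and ACSL3 at -1.2 ± 0.048. Of the cholesterol and fatty acid genes 27 of 29 were lower and 1 higher (28 and 1 adjusted over the list alone), ELOVL5 at -0.98 ± 0.047 and INSIG1 at -1.0 ± 0.051 (camera adjusted p = 6.46e-28). Replication genes were higher in 32 of 33, MCM2 by 1.15 ± 0.068 and CDC45 by 1.37 ± 0.10. Mitosis genes were higher in 28 of 29, TOP2A by 1.25 ± 0.060 and BIRC5 by 1.33 ± 0.066, each with the same count adjusted over the list alone (camera adjusted p = 9.58e-28 for replication and 3.03e-31 for mitosis). These 4 lists held with an estimated correlation (adjusted p = 0.00111, 0.0111, 0.0115 and 0.0114). Androgen-repressed genes were higher in 10 of 13, CAMK2N1 by 2.08 ± 0.086 and UGT2B15 by 3.01 ± 0.17, and lower in 2, 1 of them UGT2B28 (-1.69 ± 0.12), the same adjusted over the list alone (camera adjusted p = 2.63e-06; adjusted p = 0.0693 with an estimated correlation).

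The luminal markers were lower in 10 and higher in 1 of 15 (the same adjusted over the list alone), KRT8 at -1.05 ± 0.051 and KRT18 at -1.04 ± 0.056. The unfolded protein and amino acid stress response was lower in 17 and higher in 5 of 24 (18 and 5 adjusted over the list alone), ERN1 at -0.75 ± 0.063 and HERPUD1 at -0.58 ± 0.050. Camera called both (adjusted p = 1.56e-06 and 1.13e-06; adjusted p = 0.104 and 0.111 with an estimated correlation). Mitochondrially encoded genes were lower in 11 of 13 (11 adjusted over the list alone), MT-ND5 at -0.33 ± 0.046 (camera adjusted p = 9.90e-07; adjusted p = 0.152 with an estimated correlation). Ribosome biogenesis genes and MYC targets were higher in 11 of 20 (12 adjusted over the list alone), FBL by 0.54 ± 0.063 and MYC by 0.41 ± 0.059 (camera adjusted p = 0.000431; adjusted p = 0.208 with an estimated correlation). The p53 targets were higher in 12 and lower in 2 of 23 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00129; adjusted p = 0.0589 with an estimated correlation). Methylosome and Sm assembly genes were higher in 7 of 20, WDR77 included (adjusted over the list alone 7 higher and 1 lower; camera adjusted p = 0.0311; adjusted p = 0.404 with an estimated correlation). Immediate early and heat shock genes were lower in 10 of 16, NR4A1 at -0.85 ± 0.083, and higher in 2, 1 of them FOS (2.84 ± 0.27), the same adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.189 with an estimated correlation). Outside these lists SMS (-1.16 ± 0.049) and ODC1 (-0.99 ± 0.047) were lower, and FN1 (1.22 ± 0.054) and NTS (2.48 ± 0.21) higher. Camera did not call the polyamine, fibroblast and neuroendocrine lists that hold these genes (adjusted p = 0.0585, 0.957 and 0.256).

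The difference in R1881 response between P3 and empty-vector cells was tested as an interaction. KLK2 responded less in P3 cells (a difference of -2.03 ± 0.076 on the log2 scale), as did FKBP5 (-1.54 ± 0.071), TMPRSS2 (-1.53 ± 0.065) and KLK3 (-1.2 ± 0.067). The response of WDR77 (0.71 ± 0.10) differed upward. KLK3 was not called in the fit over all 24 libraries (edgeR adjusted p = 0.0719). In edgeR's test 4013 of 17772 genes were called, 2042 with a higher and 1971 with a lower coefficient.

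Of the androgen-induced genes 31 of 34 responded less (33 adjusted over the list alone; median difference -1.41, camera adjusted p = 2.20e-52), ACSL3 at -1.45 ± 0.068. Androgen-repressed genes differed upward in 10 and downward in 2 of 13 (11 and 2 adjusted over the list alone; camera adjusted p = 2.39e-12), the kappa opioid receptor gene OPRK1 by 3.15 ± 0.21 and CAMK2N1 by 2.35 ± 0.11. Synthesis genes of cholesterol and fatty acids differed downward in 27 and upward in 1 of 29 (the same adjusted over the list alone), ELOVL5 at -1.08 ± 0.067 and INSIG1 at -1.1 ± 0.074. Replication genes differed upward in 31 of 33 (32 adjusted over the list alone), MCM2 by 1.25 ± 0.091 and MCM4 by 1.12 ± 0.081. Mitosis genes differed upward in 28 of 29 (the same adjusted over the list alone), BIRC5 by 1.52 ± 0.088 and TOP2A by 1.31 ± 0.081. Camera gave the 3 lists adjusted p = 3.51e-30, 9.87e-35 and 1.78e-37. The p53 targets differed upward in 10, with SESN1 at 1.07 ± 0.086, and downward in 2 of 23 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000956). These 6 lists held with an estimated correlation, the highest at adjusted p = 0.047.

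Another 6 lists were called by camera, but not with an estimated correlation. Luminal markers (KRT8 at -0.84 ± 0.071) differed downward in 10 and upward in 1 of 15 (11 and 2 adjusted over the list alone). Immediate early and heat shock genes (NR4A1 at -1.06 ± 0.13) differed downward in 7 of 16 (the same adjusted over the list alone). Each of these 2 lists had adjusted p = 0.104 with an estimated correlation. The unfolded protein and amino acid stress response (ERN1 at -0.99 ± 0.092) differed downward in 14 and upward in 2 of 24 (15 and 3 adjusted over the list alone; adjusted p = 0.156 with an estimated correlation). Hypoxia and glycolysis genes (VEGFA at -1.15 ± 0.083) differed downward in 10 and upward in 3 of 21 (11 and 5 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). Ribosome biogenesis genes and MYC targets (FBL at 0.65 ± 0.087) differed upward in 9 of 20 (10 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Methylosome and Sm assembly genes (GEMIN4 at 0.60 ± 0.087) differed upward in 9 of 20 (10 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). FN1 (1.28 ± 0.075) and NTS (3.38 ± 0.25) differed upward.

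The size of the response was then measured on genes chosen in the siCtrl cells of study 2, which share no library with study 1. The 1176 genes chosen as higher with R1881 there had a median response of 1.44 in EV cells and 0.66 in P3 cells, with a median difference of -0.72 (quartiles -1.16 and -0.44), and 95.6% of them responded less in P3 cells. The edgeR interaction test called 743 of them smaller and 2 larger (camera adjusted p for the list = 7.36e-67). For the 1707 genes chosen as lower the medians were -1.08 and -0.43, the difference 0.69, and 690 responded less and 4 more (camera adjusted p = 4.72e-27). Both held with an estimated correlation (adjusted p = 5.32e-06 and 0.000456).

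**Figure D2:**
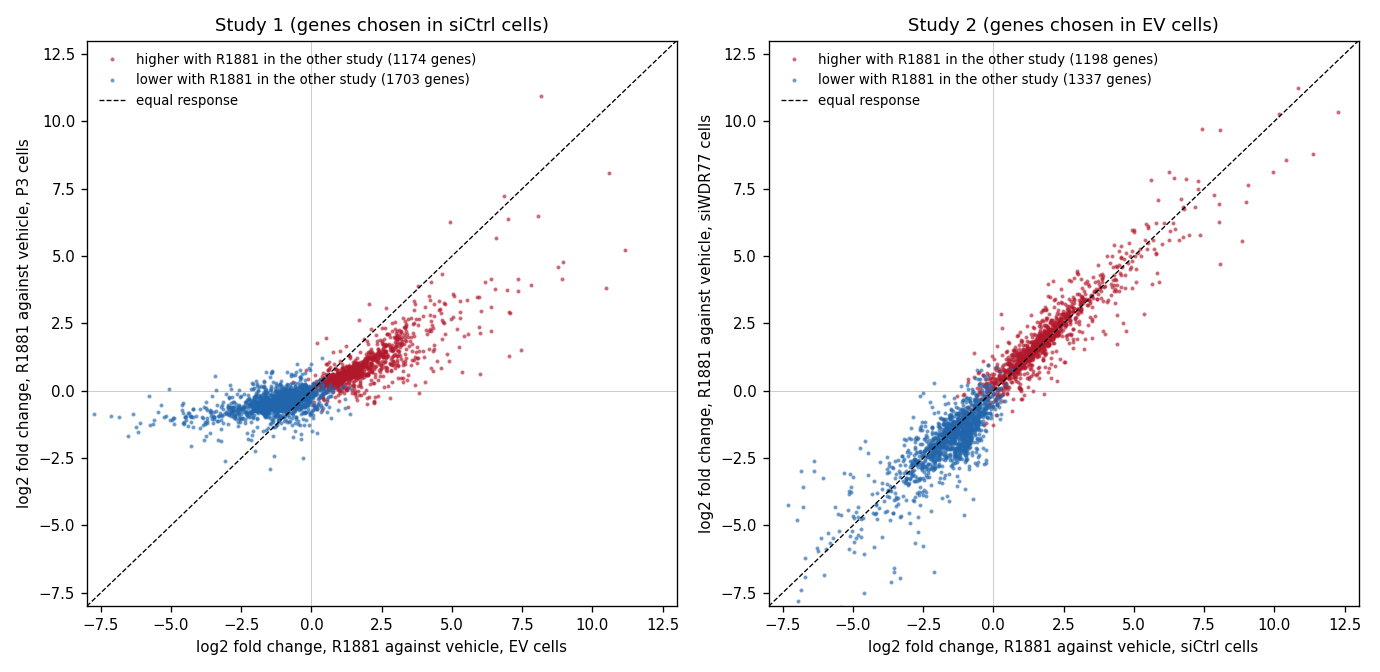
Log2 fold change with R1881 of genes chosen in the other study, with the control arm on the horizontal and the treated arm on the vertical axis, for study 1 (EV against P3) and study 2 (siCtrl against siWDR77). Each point is a gene and the line marks equal responses. Genes of the Y chromosome and XIST are left out, so the plotted sets are slightly smaller than those in the text. The median difference of the genes chosen as higher was -0.72 in study 1 and 0.11 in study 2.

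Study 2 repeated the hormone comparison in siCtrl cells. KLK2 rose by 6.38 ± 0.38, FKBP5 by 6.06 ± 0.18, KLK3 by 5.67 ± 0.54 and TMPRSS2 by 4.36 ± 0.12, and WDR77 rose by 0.55 ± 0.085 (edgeR adjusted p = 7.10e-06). Part of that WDR77 rise comes from the TMM scaling, since the group means over unscaled totals, 49.2 and 60 CPM, differ by a log2 of 0.29. The edgeR test called 9143 of 17893 genes, 4601 higher and 4542 lower, and 1235 and 1873 by at least 2-fold. ORM1 had no count in vehicle and was at least 610-fold higher, and CD200, an immunoglobulin-family membrane protein gene, had none with R1881 and was at least 97.9-fold lower. STEAP4 had 2 counts over the vehicle group, and its ratio of counts was 5980 with a 95% counting interval of 1660 to 49400.

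All 34 androgen-induced genes rose (34 adjusted over the list alone; camera adjusted p = 9.27e-31), the TGF-beta feedback gene PMEPA1 by 4.32 ± 0.072 and the elongation factor gene ELL2 by 3.6 ± 0.060. Of the androgen-repressed genes 11 of 13 fell and 2 rose (the same adjusted over the list alone; camera adjusted p = 3.86e-06), the chemokine receptor gene ACKR3 at -5.16 ± 0.10, OPRK1 at -5.04 ± 0.13 and UGT2B17 at -4.81 ± 0.078. The unfolded protein and amino acid stress response rose in 21 of 24 (the same adjusted over the list alone; camera adjusted p = 1.98e-13), the ER co-chaperone gene DNAJB9 by 2.55 ± 0.081 and HERPUD1 by 1.61 ± 0.064. These 3 lists had adjusted p = 0.0209 with an estimated correlation. Cholesterol and fatty acid genes rose in 28 and fell in 1 of 29 (the same adjusted over the list alone), ELOVL5 by 2.96 ± 0.062 and the synthase gene HMGCS1 by 2.06 ± 0.067 (camera adjusted p = 2.07e-18; adjusted p = 0.102 with an estimated correlation). Luminal markers rose in 10 and fell in 2 of 15 (the same adjusted over the list alone), KRT8 by 2.83 ± 0.067 and KRT18 by 2.65 ± 0.063. Polyamine and one-carbon genes rose in 12 and fell in 2 of 18 (the same adjusted over the list alone), SMS by 3.22 ± 0.069 and GNMT by 4.4 ± 0.10 (camera adjusted p = 4.77e-05 for both lists; adjusted p = 0.113 for the luminal and 0.102 for the polyamine list with an estimated correlation).

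The cell-cycle lists fell here too, but with wide errors. Replication genes fell in 14 of 33 (12 adjusted over the list alone; camera adjusted p = 0.00088; adjusted p = 0.699 with an estimated correlation) and mitosis genes in 22 of 29 (24 adjusted over the list alone; camera adjusted p = 2.61e-05; adjusted p = 0.611 with an estimated correlation), the kinase gene AURKB at -1.19 ± 0.24 and the securin gene PTTG1 at -1.67 ± 0.31. Library S35 of siCtrl_vehicle stood apart in these genes, with the proliferation gene MKI67 at 45.2 CPM against 117 and 119 CPM in the other siCtrl_vehicle libraries, and without it 31 replication and 26 mitosis genes fell. Of the p53 targets 13 of 23 fell and 2 rose (13 and 2 adjusted over the list alone), SESN1 at -1.93 ± 0.068 (camera adjusted p = 0.00357; adjusted p = 0.551 with an estimated correlation). NTS fell (-3.79 ± 0.28), and COPRS, a PRMT5 cofactor gene, rose by 1.02 ± 0.067, as did the ribosome biogenesis gene RRP12 (0.71 ± 0.071).

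In siWDR77 cells the hormone raised FKBP5 by 6.21 ± 0.18, KLK2 by 6.23 ± 0.37, KLK3 by 5.61 ± 0.54 and TMPRSS2 by 4.12 ± 0.12. WDR77 differed by 0.11 ± 0.10 (edgeR adjusted p = 0.378). ORM1 was at least 1160-fold higher and PLD1, a phospholipase gene, at least 87.7-fold lower, each against a group with no count. In edgeR's test 9518 genes were called, 4951 higher and 4567 lower, and 1422 and 2042 by at least 2-fold. Of the androgen-induced genes 33 of 34 rose (34 adjusted over the list alone), PMEPA1 by 4.15 ± 0.071 and ELL2 by 3.67 ± 0.060. Of the androgen-repressed genes 11 of 13 fell and 2 rose (the same adjusted over the list alone), ACKR3 at -5.88 ± 0.10 and UGT2B17 at -4.7 ± 0.075. The unfolded protein and amino acid stress response rose in 23 of 24 (the same adjusted over the list alone), DNAJB9 by 2.9 ± 0.082. Camera called the 3 lists (adjusted p = 1.61e-28, 5.63e-06 and 1.37e-13), and each had adjusted p = 0.0219 with an estimated correlation.

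Cholesterol and fatty acid genes rose in 28 and fell in 1 of 29 in siWDR77 cells (the same adjusted over the list alone), ELOVL5 by 2.88 ± 0.062 (camera adjusted p = 8.47e-18; adjusted p = 0.115 with an estimated correlation). Luminal markers rose in 11 and fell in 2 of 15, KRT8 by 2.96 ± 0.067 and KRT18 by 2.86 ± 0.063. Polyamine and one-carbon genes rose in 13 and fell in 5 of 18, SMS by 3.35 ± 0.069, each with the same counts adjusted over the list alone (camera adjusted p = 5.56e-05 for the luminal and 0.00136 for the polyamine list; adjusted p = 0.13 and 0.197 with an estimated correlation). Replication genes fell in 28 of 33 (29 adjusted over the list alone) and mitosis genes in 28 of 29 (28 adjusted over the list alone), AURKB at -2.41 ± 0.27 and the kinesin gene KIF2C at -2.48 ± 0.27 (camera adjusted p = 1.01e-08 and 1.62e-09; adjusted p = 0.498 and 0.406 with an estimated correlation). Of the p53 targets 12 of 23 fell and 3 rose (12 and 3 adjusted over the list alone), SESN1 at -1.92 ± 0.067 (camera adjusted p = 0.0232; adjusted p = 0.603 with an estimated correlation).

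The siRNA was next compared with its control in vehicle. WDR77 was lower (-1.76 ± 0.093 on the log2 scale, 3.4-fold, edgeR adjusted p = 5.74e-12). Lower with it were the lysine methyltransferase gene SETD7 (-1.56 ± 0.066), the transcription factor gene MLX (-0.89 ± 0.073) and the calsyntenin gene CLSTN1 (-0.86 ± 0.061). Higher were the splicing regulator gene PTBP2 (1.24 ± 0.080), the lectin gene REG4 (1.45 ± 0.16) and the interferon-induced gene IFI6 (1.0 ± 0.18). IFI6 was not called in the fit of the 6 libraries compared (edgeR adjusted p = 0.0891). KLK3 (0.13 ± 0.45), KLK2 (0.11 ± 0.42) and FKBP5 (0.13 ± 0.15) were not called (edgeR adjusted p = 0.951, 0.957 and 0.815). Without siCtrl_vehicle S35, where KLK3 stood at 52.6 CPM against 204 and 203 CPM in the others of its group, the values of KLK3, KLK2 and FKBP5 were -0.27, -0.30 and -0.039. TMPRSS2, at 0.41 ± 0.11, had an edgeR adjusted p of 0.112 and a DESeq2 adjusted p of 0.00216.

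The edgeR test called 273 genes between the siRNAs in vehicle, 122 higher and 151 lower, and 9 and 7 by at least 2-fold. The count was 478 without siCtrl_vehicle S35, 143 without siCtrl_vehicle S21, 105 without siWDR77_vehicle S37, 91 without siWDR77_vehicle S9 and 467 by DESeq2. Several lists were called by camera with few members called. Androgen-induced genes had 2 higher and 1 lower of 34 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00127). Androgen-repressed genes had 2 higher of 13 (5 adjusted over the list alone; camera adjusted p = 0.00403), UGT2B17 at 0.38 ± 0.061, a call lost in the fit over all 24 libraries (edgeR adjusted p = 0.259). The p53 targets had 2 lower of 23 (5 adjusted over the list alone; camera adjusted p = 2.90e-05), the apoptosis gene BAX at -0.39 ± 0.10. Ribosome biogenesis genes had 1 lower of 20 (the same adjusted over the list alone; camera adjusted p = 0.000531), FBL at -0.33 ± 0.070, and mitochondrially encoded genes 0 lower of 13 (3 adjusted over the list alone; 0.000103). Interferon response genes had 1 higher of 25 (1 adjusted over the list alone; 0.00959), which was IFI6. With an estimated correlation each of these was lost, with adjusted p = 0.468 for the repressed genes and adjusted p = 0.557 for the others. Without siCtrl_vehicle S35 the camera calls of the androgen-induced genes (median 0.073 instead of 0.14, adjusted p = 0.152), the p53 targets (-0.089 instead of -0.20, 0.115), the interferon response (0.037 instead of 0.13, 0.412) and the mitochondrially encoded genes (-0.011 instead of -0.24, 0.653) were lost too. The median moved from 0.16 to 0.040 for the androgen-repressed genes (adjusted p = 0.032) and from -0.10 to -0.17 for ribosome biogenesis (2.22e-09). BAX was not called without any one of siCtrl_vehicle S21 or S35 or siWDR77_vehicle S9, S23 or S37 (edgeR adjusted p from 0.0515 to 0.21), and FBL not without siCtrl_vehicle S21 (0.103) or siWDR77_vehicle S9 (0.138). Neither was called in the fit of the 6 libraries compared (0.0906 and 0.0605), nor BAX in that of all 24 (0.0805). The sterol regulator gene SREBF2 was lower (-0.33 ± 0.061), but not called without siWDR77_vehicle S9 (0.0609).

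No replication or mitosis gene was called by edgeR between the siRNAs in vehicle (list medians -0.043 and 0.0012, camera adjusted p = 0.757 and 0.203), although camera put the replication list higher against its median. Without siCtrl_vehicle S35, whose MKI67 level was below that of its group, both lists were lower in siWDR77 cells (median -0.30 and -0.25, camera adjusted p = 2.17e-15 and 1.89e-13), with 4 members of each called.

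In R1881 the siRNA lowered WDR77 (-2.2 ± 0.093 on the log2 scale, 4.61-fold, edgeR adjusted p = 8.47e-14). KLK3 (0.065 ± 0.44), KLK2 (-0.044 ± 0.28), TMPRSS2 (0.17 ± 0.11) and FKBP5 (0.29 ± 0.14) were not called (edgeR adjusted p = 0.961, 0.957, 0.437 and 0.283). FKBP5 was called without siCtrl_vehicle S35 (edgeR adjusted p = 0.00622). The cell-cycle factor gene E2F2 was lower (-1.69 ± 0.34), as were AURKB (-1.43 ± 0.28), the replication licensing gene CDT1 (-0.57 ± 0.12) and MYC (-0.83 ± 0.15), and the BMP regulator gene CRIM1 was higher by 1.58 ± 0.21. In edgeR's test 1291 genes were called, 698 higher and 593 lower, and 29 and 43 by at least 2-fold. The count fell to 587, 735 and 749 without siCtrl_R1881 S22, S36 or S8 and to 752 and 737 without siWDR77_R1881 S24 or S38, and was 1983 without siCtrl_vehicle S35, which changes the shared spread, the filter and the scaling together.

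Androgen-induced genes in R1881 were higher in 7 and lower in 2 of 34 (10 and 2 adjusted over the list alone), ORM1 by 0.93 ± 0.12, the prostaglandin dehydrogenase gene HPGD by 0.55 ± 0.10 and ACSL3 by 0.37 ± 0.075 (camera adjusted p = 4.21e-05). Cholesterol and fatty acid genes were higher in 6 and lower in 1 of 29 (9 and 1 adjusted over the list alone), the escort protein gene SCAP by 0.39 ± 0.070, the desaturase gene SC5D by 0.29 ± 0.056 and HMGCS1 by 0.28 ± 0.064 (camera adjusted p = 0.0050). The unfolded protein and amino acid stress response was higher in 4 of 24 (adjusted over the list alone 4 higher and 2 lower), DNAJB9 by 0.32 ± 0.072 (camera adjusted p = 0.0189). With an estimated correlation these lists were lost (adjusted p = 0.337, 0.628 and 0.367). HMGCS1 and DNAJB9 were not called without siWDR77_R1881 S24 (edgeR adjusted p = 0.0808 and 0.057). Among androgen-repressed genes UGT2B11 (1.58 ± 0.15), UGT2B28 (1.26 ± 0.15) and UGT2B17 (0.49 ± 0.083) were higher and ACKR3 lower (-0.77 ± 0.13). UGT2B17 lost its call in the fit over all 24 libraries (edgeR adjusted p = 0.194).

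Ribosome biogenesis genes and MYC targets in R1881 were lower in 9 of 20 (adjusted over the list alone 16 lower and 1 higher), FBL at -0.60 ± 0.072 and the processing factor gene BOP1 at -0.49 ± 0.088 (camera adjusted p = 1.50e-11). Replication genes were lower in 4 of 33 (16 adjusted over the list alone) and mitosis genes in 3 of 29 (14 adjusted over the list alone), with medians of -0.63 and -1.02 (camera adjusted p = 5.95e-13 and 9.71e-12). The refit without siCtrl_vehicle S35 called 26 of each. Hypoxia and glycolysis genes were lower in 5 of 21 (8 adjusted over the list alone), the glycolytic enzyme genes ENO1 at -0.32 ± 0.058, PKM at -0.27 ± 0.058 and LDHA at -0.42 ± 0.086 (camera adjusted p = 0.00319). Methylosome and Sm assembly genes were lower in 2 of 20, WDR77 and the Sm protein gene SNRPB (-0.29 ± 0.068), with 3 adjusted over the list alone (camera adjusted p = 9.80e-05). Polyamine and one-carbon genes were lower in 4 and higher in 1 of 18 (7 and 2 adjusted over the list alone), the folate enzyme gene SHMT1 at -0.37 ± 0.066 (camera adjusted p = 0.00157). Fibroblast and mesenchymal markers were lower in 2 of 8 (3 adjusted over the list alone; camera adjusted p = 0.021). With an estimated correlation these 7 lists were lost, the hypoxia and glycolysis list at adjusted p = 0.365 and the others at adjusted p = 0.337. LDHA was not called without siWDR77_R1881 S38 (edgeR adjusted p = 0.0524) and SNRPB not without siCtrl_R1881 S36 (0.0613).

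The difference in R1881 response between siWDR77 and siCtrl cells was not called for any gene in the main fit. The edgeR quasi-likelihood test called 0 of 17893 genes, with 1484 at an unadjusted p under 0.05, and DESeq2 called 56. Without siCtrl_vehicle S35 edgeR called 43. The coefficients were -0.44 ± 0.13 for WDR77, -0.065 ± 0.63 for KLK3, -0.15 ± 0.50 for KLK2, -0.24 ± 0.16 for TMPRSS2 and 0.15 ± 0.21 for FKBP5, with edgeR adjusted p from 0.294 to 0.993. KLK3 and KLK2 turned to 0.32 and 0.24 without S35. NDRG1, an androgen-induced stress gene (-0.56 ± 0.10), the kinase gene SGK1 (0.79 ± 0.16) and ACKR3 (-0.73 ± 0.15) came closest among the named genes (edgeR adjusted p = 0.0569, 0.0888 and 0.090) and were called without S35 (edgeR adjusted p = 0.000215, 0.0463 and 0.00724) and by DESeq2 (adjusted p = 0.000847, 0.0153 and 0.0135). AURKB (-1.21 ± 0.36) and CDT1 (-0.62 ± 0.16) were called with no filter on low counts (edgeR adjusted p = 0.00296 and 0.00923).

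Camera nonetheless called several lists with 0 members called by edgeR over all genes. Mitosis genes had a median difference of -1.03 (adjusted p = 1.34e-19), replication genes of -0.55 (7.84e-18; 1 lower adjusted over the list alone), ribosome biogenesis genes of -0.14 (2.26e-05) and hypoxia and glycolysis genes of -0.16 (0.000955; 4 lower and 1 higher adjusted over the list alone). Cholesterol and fatty acid genes had one of 0.11 (adjusted p = 0.00241), the unfolded protein and amino acid stress response of 0.14 (0.00407), methylosome and Sm assembly genes of -0.074 (0.00625; 1 lower adjusted over the list alone), interferon response genes of -0.14 (0.00625) and mitochondrially encoded genes of 0.16 (0.0395). With an estimated correlation these calls were lost: adjusted p = 0.339 for the mitosis, replication, hypoxia, stress and interferon lists, adjusted p = 0.373 for the ribosome and methylosome lists, adjusted p = 0.501 for the cholesterol list and adjusted p = 0.628 for the mitochondrial list. S35 moved with the cell-cycle genes, and without it 5 mitosis and 2 replication genes were called lower, with list medians of -0.72 and -0.36. Leaving it out also brought the ribosome biogenesis median to -0.088, and ended the camera calls of the interferon response (adjusted p = 0.0915) and the mitochondrially encoded genes (median -0.095, adjusted p = 0.107). The androgen-induced list was not called (median -0.058, camera adjusted p = 0.554; adjusted over the list alone 2 higher and 2 lower).

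Over the 1200 genes chosen as higher with R1881 in EV cells, the median response was 1.56 in siCtrl and 1.65 in siWDR77 cells, a median difference of 0.11 (camera adjusted p = 0.00841), which was not called on the stricter list (0.244). Over the 1341 chosen as lower the medians were -1.4 and -1.7 and the difference -0.18 (camera adjusted p = 2.27e-08). With an estimated correlation the camera adjusted p values were 0.0451 and 0.0179, and edgeR called 0 of these genes in either direction. Without siCtrl_vehicle S35 the median difference of the higher genes was 0.064 (camera adjusted p = 0.0081), with 1 called smaller and 8 larger, and that of the lower genes -0.17, with 2 smaller and 19 larger.

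Finally the effects of P3 and of the WDR77 siRNA were set side by side over the 17236 genes tested in both studies, which share no library. In R1881, 406 genes were lower with P3 and higher with the siRNA, against 134 for independent lists, and 247 were higher with P3 and lower with the siRNA, against 108 (Fisher's exact test, p = 8.48e-121 and 1.13e-41). ACSL3 and HPGD from the androgen-induced list were among the former and MYC, FBL and CDT1 among the latter. Genes called in the same direction were fewer than for independent lists, 63 higher in both against 126 and 75 lower in both against 115. Without siCtrl_vehicle S35, 507 genes were higher with P3 and lower with the siRNA (200.1 for independent lists) and 124 lower in both (212). Across genes, which are not independent replicates, the log2 fold changes had Pearson's r = -0.14 and Spearman's rho = -0.15 in R1881, -0.017 and -0.074 in vehicle. In vehicle 10 genes were higher in both against 9.53 for independent lists, 28 lower in both against 12.2, 24 lower with P3 and higher with the siRNA against 9.91 and 9 higher with P3 and lower with the siRNA against 11.7 (Fisher's exact test, p = 0.865, 2.89e-05, 3.99e-05 and 0.539). Without S35 the counts were 20, 44, 44 and 20, against 15.6, 22.3, 16 and 21.8 (Fisher's exact p = 0.232, 1.67e-05, 4.98e-10 and 0.822). Genes lower with P3 were in excess both ways, and independent lists ignore how readily genes are called, so no shared vehicle effect follows.

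The R1881 effects in the EV and siCtrl arms overlapped, with 3325 genes higher in both against 1151 for independent lists, KLK3 and FKBP5 among them, and 2907 lower in both, CAMK2N1 among them, against 1180. Pearson's r across genes was 0.82 and Spearman's rho 0.72.

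**Figure D3:**
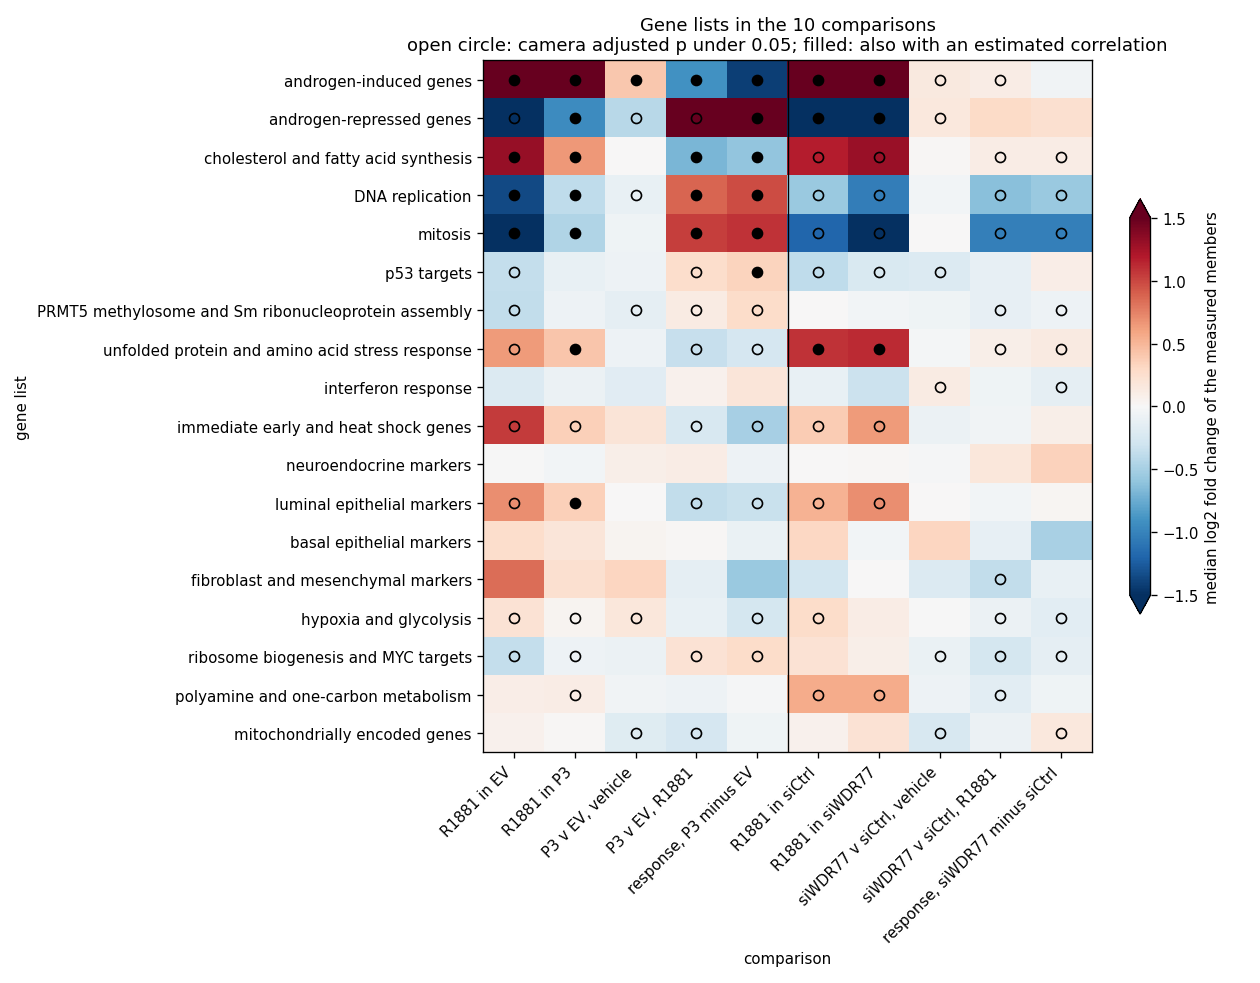
Median log2 fold change of 18 gene lists (vertical) in the 10 comparisons (horizontal), as a colour scale that ends at 1.5 in either direction. An open circle marks a camera adjusted p under 0.05, and a filled circle one that also holds with an estimated correlation. The androgen-induced list had a median of 3.17 with R1881 in EV cells, 1.66 in P3 cells and -0.91 for P3 against EV in R1881.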

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

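The splits of the libraries for counts of genes, the test of mixed RNA, the test of RNA degradation and the test on ATP5PB were chosen before the values they measure were seen, and the other tests in this part only afterwards. Each value in the next paragraphs drew attention because a hormone response differed between 2 groups of cells.

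The R1881 response differed between P3 and EV cells for 4013 genes in edgeR's test. The coefficients, P3 minus EV on the log2 scale, were 0.71 for WDR77, -1.2 for KLK3, -2.03 for KLK2, -1.53 for TMPRSS2 and -1.54 for FKBP5. Among members of the lists they were -1.45 for ACSL3, 2.35 for CAMK2N1, 3.15 for OPRK1, -1.08 for ELOVL5, -1.1 for INSIG1, 1.25 for MCM2 and 1.12 for MCM4. Further values were 1.52 for BIRC5, 1.31 for TOP2A, -0.84 for KRT8, 1.28 for FN1, 3.38 for NTS, -1.15 for VEGFA, 1.07 for SESN1, 0.65 for FBL, -0.99 for ERN1, 0.60 for GEMIN4 and -1.06 for NR4A1. The medians of lists that camera called were -1.41 for androgen-induced genes, 2.35 for androgen-repressed genes, -0.59 for cholesterol and fatty acid synthesis, 0.97 for DNA replication and 1.08 for mitosis. They were 0.34 for p53 targets, 0.28 for the methylosome and Sm assembly, -0.25 for the unfolded protein and amino acid stress response and -0.50 for immediate early and heat shock genes. The other 3 were -0.34 for luminal markers, -0.26 for hypoxia and glycolysis and 0.28 for ribosome biogenesis and MYC targets. Between siWDR77 and siCtrl cells they were 0.11 for cholesterol and fatty acid synthesis, -0.55 for DNA replication, -1.03 for mitosis and -0.074 for the methylosome and Sm assembly. They were 0.14 for the unfolded protein and amino acid stress response, -0.14 for the interferon response, -0.16 for hypoxia and glycolysis, -0.14 for ribosome biogenesis and 0.16 for mitochondrially encoded genes. All 9 calls were lost with an estimated correlation (adjusted p = 0.339 to 0.628), as were the 6 of study 1 from the methylosome to ribosome biogenesis (0.104 to 0.17), and the interferon and mitochondrial calls also ended without S35 (adjusted p = 0.0915 and 0.107). Over the genes chosen in the other study as higher and as lower, the median differences were -0.72 and 0.69 in study 1 and 0.11 and -0.18 in study 2.

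The response differed between the 2 control arms too, for 3185 of 18999 genes in an edgeR fit of all 24 libraries, 1148 with a higher and 2037 with a lower coefficient. EV minus siCtrl, the values were -0.53 for WDR77, -3.32 for KLK3, -3.21 for KLK2, -1.23 for TMPRSS2 and -1.01 for FKBP5. The arms differ in the study, the transfection and the kind of nucleic acid together.

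For comparisons of 2 groups there are 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes. The real counts were 9130 with R1881 in EV cells (highest other 0) and 3726 in P3 cells (0), and 9143 in siCtrl cells (0) and 9518 in siWDR77 cells (0). Between arms they were 2809 and 6572 for P3 against EV in vehicle and R1881 (0 and 1), and 273 and 1291 for the siRNAs (2 and 0). For the difference in response in study 1, 3 of 100 splits gave as many as the 4013 genes called, and the highest other gave 6692. That split exchanged the arm labels of every R1881 library and of no vehicle library, which adds the effects of P3 in the 2 hormone states instead of subtracting them, so its count points to the arms themselves. The median of the higher genes was as large in 1 split of 100 (0.725, highest other 0.641), and that of the lower genes in 13 (0.687, highest other 0.822). All 12 others kept or exchanged the arm labels of every R1881 library, so they hold the effect of P3 in R1881 whole, and the 85 splits that mixed these labels reached at most 0.35. The count for the lower genes therefore does not measure chance alone. In study 2 the 0 genes called by edgeR (1484 at an unadjusted p under 0.05, and 56 called by DESeq2) were reached by 100 of 100 splits, as a count of 0 must be, so this says nothing about chance. The highest other count, 1776, again came from exchanging the R1881 arms and so points to the siRNA arms themselves. The medians of the higher and lower genes were reached by 18 and 6 (0.112 and 0.179, highest others 0.226 and 0.207). Of the 17 and 5 others, 12 and 5 kept or exchanged every R1881 label, and the 86 splits that mixed these labels reached at most 0.148 and 0.15. Chance cannot be excluded for the higher genes, and for the lower genes the count again does not measure chance alone.

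The first pattern weighed is the smaller hormone response of P3 cells. A scaling difference is argued against by the genes chosen as lower, whose median difference of 0.69 has the opposite sign to the higher genes'. Higher starting levels in P3_vehicle are argued against as the whole cause by the higher genes' median between P3 and EV in R1881. It was -0.59 (bootstrap over genes, not libraries, -0.61 to -0.56). A mix of RNA like that of EV_R1881 and P3_vehicle was tested too. At least 1.5-fold outside both groups lay 8 called genes: WDR77 and SPRY4, a signalling inhibitor gene, above and 6 below. SPRY4 was named after its values were seen. A share of the EV_R1881 profile of 0.411 (0.4 to 0.423 by library) places higher genes and of 0.456 (0.446 to 0.483) lower genes. A mix alone would give a single share, but by the test chosen beforehand 8 genes outside are few enough for one. Mixed samples, an even partial response, a mix of responding and non-responding cells and an effect of the peptide stay open.

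The second pattern is library S35 of siCtrl_vehicle, which stood apart from the other 2 of its group. Its CPM was 380 for GDF15 against 180 and 162 in S21 and S7, 378 against 235 and 242 for the p53 target CDKN1A, 12.9 against 6.71 and 6.08 for the heme oxygenase gene HMOX1, 52.6 against 204 and 203 for KLK3 and 45.2 against 117 and 119 for MKI67, genes chosen after their values were seen. Loss of long transcripts is argued against by the Spearman correlation of its deviations with exon length (-0.0386), lower depth by the rank of its total among the 12 libraries of study 2 (number 6 from the lowest), and a swap with an siWDR77 library by its WDR77 level, 3.13 times the highest of siWDR77_vehicle. No biological explanation was tested, since the labels give none for a single library.

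The third pattern is WDR77 mRNA in P3 cells given R1881, 0.64 above EV cells (95% interval 0.49 to 0.80). Reads from a construct expressed alike with and without hormone are argued against by the difference in vehicle, -0.063 (interval -0.22 to 0.093). Reads shared with the overlapping gene ATP5PB are argued against by its own difference in R1881, -0.093 (interval -0.22 to 0.034). A construct that is itself raised by androgen, for which no sequence was used here, and a rise of the cells' own WDR77 stay open.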

How the results depend on the processing

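The added fits without S35 named above were chosen after the data were seen, and the other alternatives of this part before. The 242 values of named genes were computed under 3118 alternatives: 3055 kept their direction and their side of the threshold, 30 kept the direction but were no longer called, 19 were newly called and 14 changed sign, each on leaving out 1 library and each for a value that was not called. Of 132 counts under alternatives to the 10 counts of called genes, 106 stayed within 1.5 times. RLE size factors changed no call of a named gene and moved no count beyond that range. The 109 list results followed in the text had 376 list tests under alternatives. Of these 265 kept their side, 102 lost the call, 71 of them with an estimated correlation between genes, 3 gained it and 6 changed direction. The other 71 list results, a few of them given briefly above, had 254 such tests. Of these 221 kept their side, 21 gained a call, 14 of them by fry, and 12 changed direction. Except where the construction shows it, the cause was not tested.

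In the comparison of the siRNAs in vehicle, with 273 genes called by edgeR, 422 were called without the filter on low counts, 467 by DESeq2, 127 in a fit of the 6 libraries alone, which leaves fewer degrees of freedom, and 491 in a fit of all 24 libraries. For the difference in response between the siRNAs edgeR called 0 genes (1484 at an unadjusted p under 0.05), against 112 without the filter, 56 by DESeq2 and 40 in the fit of 24 libraries. Leaving out 1 library gave ranges of 1344 (without P3_vehicle S5) to 3124 (P3_vehicle S19) for P3 against EV in vehicle, 91 (siWDR77_vehicle S9) to 478 (siCtrl_vehicle S35) for the siRNAs in vehicle, 587 (siCtrl_R1881 S22) to 1983 (siCtrl_vehicle S35) for the siRNAs in R1881 and 0 to 43 (siCtrl_vehicle S35) for the difference in response between them. The other 6 counts stayed within 1.5 times with 1 library less. Under the alternatives that keep all libraries, so did all counts except those given for the siRNAs in vehicle and for the difference in response between them. At the stricter threshold, genes lower in both studies in R1881 were 0.789 times the number for independent lists (Fisher's exact p = 0.199). The larger response of siWDR77 cells in the higher genes was not called there (camera adjusted p = 0.244). Both rest on fewer genes.

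Values of genes that changed sign ranged, with 1 library left out, for WDR77 from -0.0026 (without EV_R1881 S30) to 0.11 (EV_vehicle S29) with R1881 in EV cells, and from -0.13 (P3_vehicle S19) to 0.0088 (P3_vehicle S33) for P3 against EV in vehicle. For the siRNAs in vehicle they ranged from -0.27 (siCtrl_vehicle S35) to 0.39 (S7) for KLK3, -0.30 (S35) to 0.48 (S7) for KLK2 and -0.039 (S35) to 0.26 (S21) for FKBP5, and for the difference in response from -0.33 (S7) to 0.32 (S35) for KLK3 and -0.52 (S7) to 0.24 (S35) for KLK2. For the siRNAs in R1881 they ranged from -0.10 (siWDR77_R1881 S24) to 0.038 (S38) for KLK2.

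Among the 109 list results followed in the text, fry gave the opposite direction for fibroblast and mesenchymal markers (adjusted p = 0.874) with R1881 in EV cells. Without S35, camera gave the opposite direction for DNA replication (2.17e-15) and mitosis (1.89e-13) between the siRNAs in vehicle, and for androgen-induced genes (0.167) and mitochondrially encoded genes (0.107) in the difference in response between the siRNAs. Of these only the mitochondrially encoded genes had been called with all libraries. Of the other list results 5 gained a camera call without S35: mitochondrially encoded genes with R1881 in siCtrl cells (8 called higher, adjusted p = 0.00246) and siWDR77 cells (0.0181) and between the siRNAs in R1881 (0.00921), and the methylosome (0.0207) and polyamine lists (0.0211) between the siRNAs in vehicle.

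With the run of the sample number as a replicate block, the difference in response between the siRNAs called 16 genes, and the other 9 counts stayed within 1.5 times. Of the 242 gene values 241 kept their side. Among the 109 list results followed in the text only DNA replication between the siRNAs in vehicle changed direction (camera adjusted p = 0.885). NDRG1 was newly called in that difference (edgeR adjusted p = 0.0164). In the 3 comparisons whose libraries the runs pair, the block changed no call of a named gene or list. Of the 11 genes with a higher coefficient under the block, 7 had a lower one in P3 cells (1.43 for independent lists, Fisher's exact p = 0.000126) and 1 a higher one, and of the 5 with a lower coefficient 2 had a higher one in P3 cells (0.69, p = 0.143) and 3 a lower one too (0.649, p = 0.0179). Over all groups, deviations from the group means correlated at over 0.1 in 13 of 18 pairs of one run in study 1 (median 0.242) and in 10 of 18 in study 2 (0.14), so the runs do not pair all groups. As a hint from the data and not the design, 11 of 12 libraries of study 1 and 4 of 12 of study 2 correlated best with one of their own run. With 200 genes changed, 1.25-fold changes were simulated at this depth and group size. They were recovered in 36% of genes for P3 against EV in R1881 and 10% for the difference in response in study 1. For the siRNAs it was 20% in R1881 and 2% for the difference in response. Recovery with more changed genes was not simulated.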

Other observations

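Tests between the 2 control arms and fits without library S35 were chosen after the data were seen. The 4 androgen-induced genes followed throughout stood higher in EV than in siCtrl cells when no hormone was given, in the edgeR fit of all 24 libraries with 3 libraries per group. The kallikrein gene KLK3 was higher by 3.08 ± 0.34 (SE) on the log2 scale (adjusted p = 2.21e-06), KLK2 by 3.55 ± 0.25 (1.15e-08), TMPRSS2 by 1.07 ± 0.085 (6.70e-10) and FKBP5 by 1.0 ± 0.12 (1.53e-06). With R1881 the same 4 genes were not called between these arms, with KLK3 at -0.24 ± 0.31 (0.672), KLK2 at 0.34 ± 0.19 (0.251), TMPRSS2 at -0.16 ± 0.082 (0.18) and FKBP5 at -0.0035 ± 0.10 (0.991). WDR77 was higher in EV cells in vehicle, by 0.37 ± 0.078 (0.000236), and not called in R1881. Of 18999 genes, 6558 were called between the control arms in vehicle and 3650 in R1881. These arms differ in study and transfection together, and no biological explanation was tested.

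Immediate early and heat shock genes rose as a list with R1881 in siCtrl cells (8 of 16 called higher, 0 lower, camera adjusted p = 0.0112, and 0.229 with an estimated correlation) and in siWDR77 cells (9 higher, 0 lower, 0.0153, and 0.264). The nuclear receptor gene NR4A1 rose by 3.1 ± 0.17 (SE, log2 scale) in siCtrl and 3.26 ± 0.17 in siWDR77 cells (edgeR adjusted p = 7.64e-09 and 5.24e-09), and DUSP1, a phosphatase gene, by 1.24 ± 0.086 and 1.28 ± 0.086 (7.16e-12 and 3.28e-12). Hypoxia and glycolysis genes were called higher as a list in siCtrl cells (13 higher and 6 lower of 21, 0.0261, and 0.611 with an estimated correlation) and in P3 cells (7 and 1, 0.0274, and 0.427). The hexokinase gene HK1 rose by 1.52 ± 0.057 in siCtrl and by 0.84 ± 0.049 in P3 cells (edgeR adjusted p = 3.77e-17 and 1.18e-17). Ribosome biogenesis and MYC target genes were called lower in P3 cells given R1881 (6 of 20 lower, 0 higher, 0.0274, and 0.427 with an estimated correlation), with MYC at -0.25 ± 0.057 and FBL, a methyltransferase gene of the nucleolus, at -0.25 ± 0.061 (edgeR adjusted p = 0.000793 and 0.00241). MYC was not called in the fit of all 24 libraries (edgeR adjusted p = 0.102).

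Without S35, 43 genes differed in response between the siRNAs. Of the 29 with a lower coefficient in siWDR77 cells, 21 had a higher coefficient in P3 cells (3.39 for independent lists, Fisher's exact p = 4.11e-14), and of the 14 with a higher one, 10 had a lower one in P3 cells (1.58, p = 2.10e-07). Overlaps with the same sign were 2 (1.64) and 2 (3.27). Genes are not independent replicates, and with S35 edgeR called 0 genes in study 2 (1484 at an unadjusted p under 0.05, and 56 called by DESeq2), so the main fit gives no such overlap.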
